A study of Escherichia coli with 2 samples.

How the data were processed

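RNA from Escherichia coli K-12 strain W3110 was compared on 2 two-colour Agilent oligonucleotide arrays, each holding RNA labelled as hydrogen peroxide treated beside RNA labelled as untreated control. Array 1, titled replicate 1, carried the labelled control in Cy5 and the labelled H2O2 RNA in Cy3. Array 2, titled replicate 2, carried the same conditions with the dyes exchanged. Both arrays lay on 1 slide and shared 1 scan, per the file headers, so no batch could be separated. The titles number the arrays as replicates 1 and 2, yet both descriptions carry the number 1. The p-values of single genes therefore measure only the spread between these 2 arrays, which may be technical.

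The deposited array files gave spot intensity, the mean pixel brightness in Cy3 and Cy5 and the median brightness of the local background, neither of them background-subtracted, per the file headers. They also gave processed intensity values that had been background-subtracted, spatially detrended and dye-normalized within the array, per the file headers. The image analysis used Agilent Feature Extraction 9.5.3.1, per the submitters' processing notes. The deposited series table held the log10 ratio of processed Cy5 over processed Cy3, not turned for the dye exchange. Its values were equal to the log10 ratio in the deposited array files, with a largest difference of 0.

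Spot intensity was corrected with normexp (offset 50) and each array was normalized by loess, with control spots and spots marked as outliers given no weight. The fit thus included probes annotated to strains other than K-12, which held 7007 of the 11494 spots that were not controls. The offset pulls ratios of dim genes towards 0, so folds of genes dim in a channel are understated. Of 15744 spots, 11494 were not controls and belonged to 10691 probes. A probe was given to K-12 when its systematic name or description carried a K-12 b number, which held for 4286 probes of 4261 genes. Of these genes, 4095 matched a locus tag of the reference table of assembly ASM584v2, which was used only for names, and 166 did not. Outlier spots numbered 32 on array 1 and 34 on array 2, and no spot was saturated. Spots of a probe were averaged, a probe was kept if it was well above background in the channel of at least 1 condition on both arrays, and a gene was the mean of its kept probes. The filter removed 120 genes and left 4141, of which 4119 had 1 probe and 22 had more. Without the rule on signal 4254 genes stayed, so a few of the 120 were lost to spots marked as outliers. Between 94.0% and 97.9% of K-12 spots were well above background in each channel and array. The number of arrays, 2, limits the precision.

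Log2 ratios were turned to labelled H2O2 over labelled control on each array and tested with limma 3.58.1 in R 4.3.3, as a 2-sided moderated test of the mean over the exchanged arrays with Benjamini-Hochberg adjustment over all genes tested. Genes under an adjusted p of 0.05 are called higher or lower. limma estimated a single variance for all genes, with a standard deviation of 0.392 and a standard error of 0.277 for every gene mean, so each call rests on pooling the spread over genes. The very small p-values of genes exist only under that pooling. Some other processing gave the shared variance a finite weight. Its prior degrees of freedom were 10.7 with the Agilent processed signals, 9.9 with loess fitted on K-12 probes and 4.1 with median centring on all probes. The SD printed beside a value is that of the gene's own log2 ratios on the 2 arrays. A fold is given as a lower bound where a channel lay at background, which held for 51 genes. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 28 lists. Camera sets the genes of a list against all other genes, so its p-values measure spread across genes, not between arrays. As an alternative the correlation was estimated from the data, which left the test 1 residual degree of freedom and little power. The lists were OxyR regulon, SoxRS regulon, SOS regulon, heat shock, envelope stress, RpoS general stress, glutamate acid resistance, iron acquisition, Isc iron-sulfur assembly, peroxide scavenging, thiol redox, DNA base repair, cysteine and sulfur assimilation, methionine, arginine, histidine and branched-chain amino acid synthesis, purine and pyrimidine synthesis, ribosomal proteins, ATP synthase, NADH dehydrogenase I, TCA cycle, anaerobic respiration and fermentation, flagella and chemotaxis, copper and zinc handling, phage shock, toxin-antitoxin and cold shock. They held 540 different genes, of which 514 were measured.

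The design, the tests, the gene lists, the rule for named genes and all alternatives but those said to be added later were set before the data were examined. The named genes were 16 fixed stress genes, the 10 largest called changes in each direction and up to 3 members of each list with the largest change, 101 measured genes in all. The fixed gene oxyS, was not measured here. Alternatives covered background correction, the normexp offset, within-array and between-array normalization, the filter, probe averaging, the variance prior, the threshold, the deposited ratios and leaving out each array. The functions were tested on simulated data drawn on the real backgrounds and intensities over 4141 genes, for the comparison of the labelled channels. Of 100 genes changed 2-fold, 55% were recovered, and of 100 genes changed 4-fold, 100% were recovered. The simulated noise had the same size for every gene, as the test assumes, and only these genes changed. The recovery thus checks the functions and cannot show how reliable the real calls are. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.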

Results

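Total RNA was measured from E. coli W3110, a K-12 laboratory strain, grown without shaking in minimal medium at 37 °C to an OD600 of 0.1. Cells were sampled after 10 min with or without 1% (v/v) hydrogen peroxide, under conditions the labels call anaerobic. RNA from both conditions was hybridized together on each of 2 arrays with exchanged dyes, which together form 1 group. The median spot intensity on array 1 was 773 in Cy3 and 472 in Cy5, and on array 2 it was 420 in Cy3 and 1250 in Cy5. Median local background lay between 45 and 56.5.

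The comparison asked which transcripts differ after 10 min of peroxide. Values are log2 ratios of the RNA labelled H2O2 over the RNA labelled control, so a negative value means a lower level in the RNA labelled H2O2. In this orientation katG, the peroxide-inducible catalase, was -5.15 ± 0.45 (SD, n = 2 arrays), a 35.4-fold higher level in the RNA labelled control. The iron-sulfur scaffold gene sufA was -8.76 ± 0.16 (SD, n = 2), a 433-fold higher level in the RNA labelled control, and dps, the DNA-protecting ferritin-like protein, was -7.03 ± 1.64 (SD, n = 2). These genes are known to be induced by peroxide, so their direction went against the channel labels. If the labels were exchanged, every sign given here would turn. By contrast, genes of pyrimidine and purine synthesis were among those with the largest higher values, and the largest was that of carA, a subunit of carbamoyl phosphate synthetase, at 5.59 ± 0.34 (SD, n = 2).

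Of 4141 genes tested, 2108 passed, 1074 of them higher and 1034 lower in the RNA labelled H2O2 (limma, Benjamini-Hochberg adjusted). At least 2-fold changes in the same labelled direction on both arrays were seen for 1039 genes, 565 higher and 474 lower. Only 2 genes changed at least 2-fold in the same dye direction on both arrays. Across genes, which are not independent replicates, the Cy5 over Cy3 ratios of the arrays correlated at -0.92 (Pearson) and -0.88 (Spearman). Opposite signs on the arrays were seen for 7 of the called genes. The calls rest on a variance shared by all genes: an ordinary test with 1 residual degree of freedom, added after the data were seen, passed 2 genes, matP and lepB, with 776 under an unadjusted p of 0.05 where 207 are expected by chance. The main loess fit included probes for other strains, and loess fitted on K-12 probes well above background gave 1092 genes higher and 1151 lower. In place of loess, centring each array on the median of all its probes, other strains again included, moved the median of all genes to 0.59. It gave 1885 genes higher and 384 lower. Centring on K-12 probes well above background, added after the data were seen, gave a median of -0.058 with 1384 higher and 1342 lower.

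**Figure D1:**
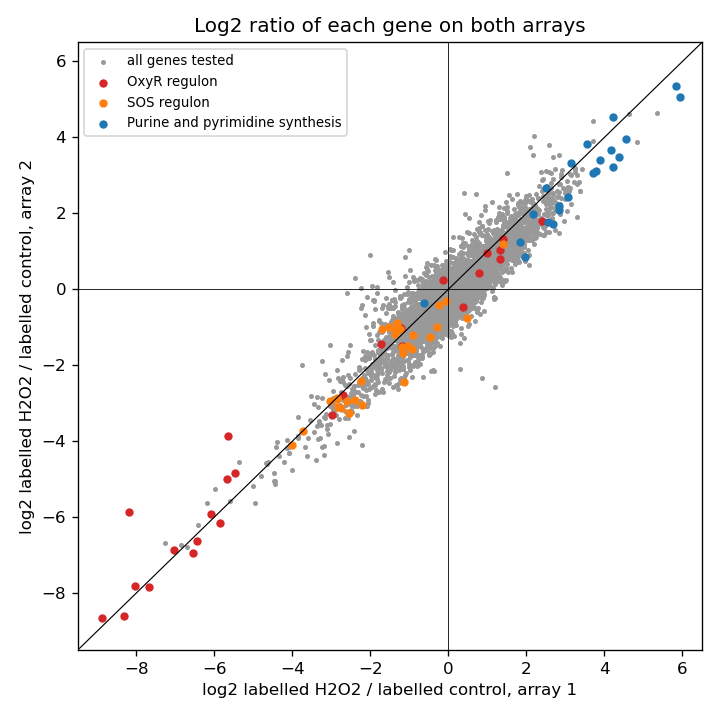
Log2 ratio of labelled H2O2 over labelled control for each of 4141 genes on array 1 (x axis) and array 2 (y axis), with the diagonal of equal values. Members of the OxyR and SOS lists lie mostly at negative values on both arrays and those of purine and pyrimidine synthesis at positive values, and the Cy5 over Cy3 ratios correlated at -0.92 because the dyes were exchanged.

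The OxyR regulon, the genes under the peroxide-sensing activator, had 18 of 26 measured members lower and 5 higher, with a median log2 ratio of -3.95 (camera adjusted p = 5.73e-33). Adjusted over the list alone, 18 were lower and 6 higher, and the adjusted p was 0.557 with an estimated correlation. The whole suf operon was lower, with sufB at -8.46 ± 0.21, sufC at -7.92 ± 0.17, sufD at -7.75 ± 0.11 and sufS at -6.95 ± 0.12 (SD, n = 2). The glutaredoxin gene grxA was -6.75 ± 0.29 (adjusted p = 5.49e-120), a 108-fold higher level in the RNA labelled control. The manganese transporter gene mntH was -6.00 ± 0.13, the thioredoxin gene trxC -6.00 ± 0.22, and the alkyl hydroperoxide reductase genes ahpF and ahpC -5.35 ± 0.48 and -4.76 ± 1.25 (SD, n = 2). The iron regulator gene fur was -1.12 ± 0.15. The gene of the regulator itself, oxyR, was higher in the RNA labelled H2O2, at 1.06 ± 0.36 (adjusted p = 0.000431).

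**Figure D2:**
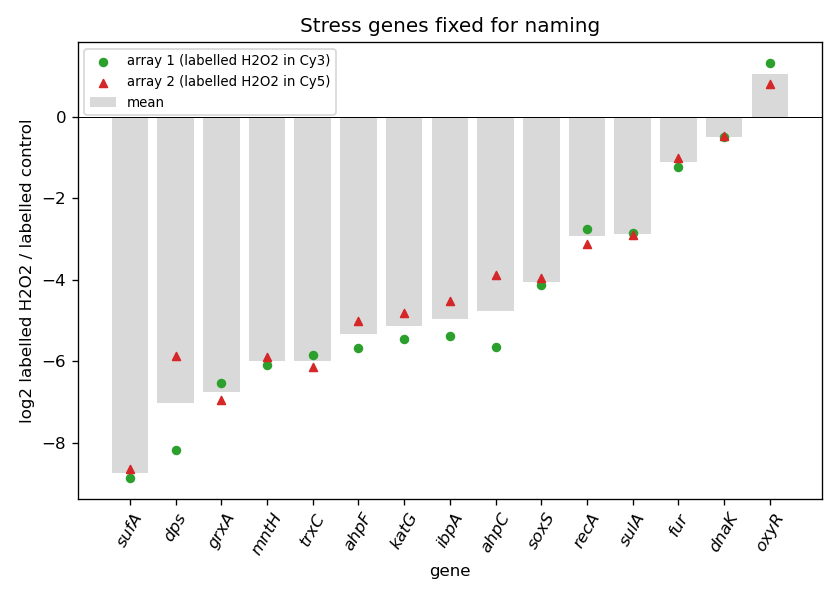
Log2 ratio of labelled H2O2 over labelled control for 15 stress genes fixed before the data were examined, with bars for the mean and points for each of the 2 arrays. The values run from -8.76 for sufA to 1.06 for oxyR, and dnaK at -0.49 did not pass.

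The SoxRS regulon, which answers redox-cycling compounds, had 17 of 26 members lower and 5 higher (median -1.10, camera adjusted p = 1.15e-06). Adjusted over the list alone, 18 were lower and 5 higher, and the adjusted p was 0.557 with an estimated correlation. Manganese superoxide dismutase, sodA, was -6.80 ± 0.09, fumarase C, fumC, -6.31 ± 0.16, aconitase A, acnA, -4.21 ± 0.16, and the activator gene soxS -4.05 ± 0.12 (SD, n = 2). The median turned to 0.17 when centred on all probes, below the 0.59 of all genes in that scaling, and was -0.49, still passing, when centred on K-12 probes. Peroxide scavenging genes were lower in 6 of 9 and higher in 2 (median -1.59, camera adjusted p = 0.000169), with the same counts adjusted over the list alone. This list shares katG, the ahp genes and yhjA with the OxyR list, and the value of yhjA is its median. It did not pass on ranks, and had an adjusted p of 0.557 with an estimated correlation. Thiol redox genes were lower in 7 of 12, and in 7 adjusted over the list alone, with none higher (median -0.88, camera adjusted p = 0.000173). Its adjusted p was 0.557 with an estimated correlation, and its median turned to 0.38 when centred on all probes, against 0.59 for all genes, where the list did not pass, and was -0.27, still passing, when centred on K-12 probes. The thiol redox list shares grxA, trxC and gor with the OxyR list. Besides grxA and trxC, thioredoxin 1, trxA, was -1.92 ± 0.16.

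The SOS regulon, the DNA damage response, had 27 of 31 members lower and 1 higher, with the same counts adjusted over the list alone (median -1.38, camera adjusted p = 7.67e-11, adjusted p = 0.557 with an estimated correlation). The SOS median was -0.16 when centred on all probes, against 0.59 for all genes, and -0.81 when centred on K-12 probes, passing in both. The damage-inducible gene dinD was -4.05 ± 0.07, the recombination gene recN -3.73 ± 0.02, yebG -2.99 ± 0.08, the recombinase gene recA -2.93 ± 0.26, and the division inhibitor gene sulA -2.88 ± 0.03 (SD, n = 2). DNA base repair genes did not pass as a list (median 0.15, 0.24 on array 1 and 0.17 on array 2, camera adjusted p = 0.947), with 4 of 16 higher and 3 lower, the same adjusted over the list alone. Within it, endonuclease IV, nfo, was -3.42 ± 0.23 and exonuclease III, xthA, -1.69 ± 0.04, while the adenine glycosylase gene mutY was 1.58 ± 0.03 (SD, n = 2). Toxin-antitoxin genes were lower in 12 of 16 with none higher, the same adjusted over the list alone (median -1.32, camera adjusted p = 0.00068, adjusted p = 0.557 with an estimated correlation). This list shares dinJ, yafN and yafO with the SOS list. The toxin-antitoxin median was -0.29 when centred on all probes, against 0.59 for all genes, and -0.94 when centred on K-12 probes. The toxin gene mqsR was -2.77 ± 0.40, its antitoxin gene mqsA -2.24 ± 0.13, and yafN -2.77 ± 0.23 (SD, n = 2).

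Iron acquisition genes were lower in 23 of 33 and higher in 1, the same adjusted over the list alone (medians of -1.60 and -2.22 on arrays 1 and 2, camera adjusted p = 9.6e-14, adjusted p = 0.557 with an estimated correlation). The bacterioferritin-associated ferredoxin gene bfd was -5.10 ± 0.11, the enterobactin synthesis gene entC -4.38 ± 0.24, and the ferrichrome receptor gene fhuA -4.21 ± 0.16 (SD, n = 2). The Isc iron-sulfur assembly list had 5 of 8 genes lower and none higher, the same adjusted over the list alone (median -1.76, camera adjusted p = 0.000394, adjusted p = 0.557 with an estimated correlation). The list did not pass when centred on all probes, with a median of -0.55 against 0.59 for all genes. It passed when centred on K-12 probes, with a median of -1.20. The repressor gene iscR was -3.91 ± 0.33, the cysteine desulfurase gene iscS -3.29 ± 0.35, and the scaffold gene iscU -3.22 ± 0.17 (SD, n = 2). Copper and zinc handling had 3 of 14 higher and 3 lower, the same adjusted over the list alone, and did not pass (camera adjusted p = 0.973), with a median of -0.17 (0.053 on array 1 and -0.29 on array 2) and a mean of -0.016 against an upward test. In it, the zinc-binding protein gene znuA was 2.64 ± 0.25, the copper regulator gene cueR -1.86 ± 0.42, and the copper exporter gene copA -1.61 ± 0.16 (SD, n = 2).

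Heat shock chaperones and proteases were lower in 11 of 19 with none higher, the same adjusted over the list alone (median -0.76, camera adjusted p = 0.00068, adjusted p = 0.557 with an estimated correlation). The median turned to 0.44 when centred on all probes, against 0.59 for all genes, where the list did not pass, and was -0.21, still passing, when centred on K-12 probes. The small heat shock protein genes ibpB and ibpA were -5.62 ± 0.50 and -4.96 ± 0.60, and the disaggregase gene clpB -1.89 ± 0.12 (SD, n = 2). The chaperone gene dnaK was -0.49 ± 0.02 and did not pass (adjusted p = 0.131). RpoS general stress genes were lower in 10 of 21 and higher in 1, the same adjusted over the list alone (median -0.59, camera adjusted p = 0.0478, adjusted p = 0.81 with an estimated correlation). Its median was -0.47 on array 1 and -1.02 on array 2, and the list did not pass when centred on all probes or on K-12 probes, or with a trended robust prior. The RpoS median was -0.077 when centred on all probes and -0.73 when centred on K-12 probes. Its largest members were osmC at -2.49 ± 0.09, osmY at -1.77 ± 0.29 and talA at -1.42 ± 0.21 (SD, n = 2). Phage shock genes did not pass (median -1.09, camera adjusted p = 0.107), with 4 of 7 lower and 1 higher, the same adjusted over the list alone, and stood at percentile 1.33 of random lists. Their median turned to 0.12 when centred on all probes and was -0.53 when centred on K-12 probes. Of these, pspD was -1.98 ± 0.20, pspB -1.94 ± 0.27 and pspC -1.45 ± 0.46 (SD, n = 2). Envelope stress genes were higher in 8 of 13 and lower in 2 (median 1.26, camera adjusted p = 0.0194). Adjusted over the list alone, 9 were higher and 2 lower, and the adjusted p was 0.557 with an estimated correlation. The envelope stress sigma factor gene rpoE was 2.73 ± 0.51, the periplasmic chaperone gene fkpA 1.98 ± 0.05, and rseC 1.91 ± 0.40 (SD, n = 2). Glutamate acid resistance genes were higher in 8 of 11 with none lower, the same adjusted over the list alone (median 0.96, camera adjusted p = 0.0495, adjusted p = 0.822 with an estimated correlation). The list did not pass at a normexp offset of 16 or with the stricter filter on both channels, and its median stood at percentile 96.0 of random lists, short of the outer 2.5%. The regulator gene gadW was 1.60 ± 0.0034, the acid chaperone gene hdeB 1.58 ± 0.38, and hdeD 1.40 ± 0.51 (SD, n = 2).

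Purine and pyrimidine synthesis was higher in 21 of 22 genes with none lower, the same adjusted over the list alone (median 3.31, camera adjusted p = 4.7e-25, adjusted p = 0.557 with an estimated correlation). The dihydroorotate dehydrogenase gene pyrD was 5.50 ± 0.62, the aspartate carbamoyltransferase genes pyrB and pyrI 4.37 ± 0.21 and 3.93 ± 0.36, and the purine genes purM and purE 4.26 ± 0.42 and 3.93 ± 0.63 (SD, n = 2). Outside the list, the cytosine uptake and deamination genes codB and codA were 4.99 ± 0.51 and 4.36 ± 0.66, and the uracil transporter gene uraA 4.62 ± 0.015 (SD, n = 2). The carA level was 48-fold higher in the RNA labelled H2O2 (adjusted p = 6.21e-84). Cold shock genes were higher in 7 of 10 and lower in 3, the same adjusted over the list alone (median 1.87, camera adjusted p = 0.00455, adjusted p = 0.557 with an estimated correlation). The list did not pass when centred on all probes, with a median of 3.025 against 0.59 for all genes. It passed when centred on K-12 probes, with a median of 2.37. The RNA chaperone genes cspA and cspE were 4.06 ± 0.51 and 2.93 ± 1.17, and the initiation factor gene infA 2.07 ± 0.22 (SD, n = 2).

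Anaerobic respiration and fermentation genes were higher in 22 of 46 and lower in 2, the same adjusted over the list alone (median 0.55, 0.82 on array 1 and 0.45 on array 2, camera adjusted p = 0.00105, adjusted p = 0.724 with an estimated correlation). The nitrate transporter gene narK was 3.21 ± 0.06, the nitrate reductase gene narG 2.17 ± 0.02, and the nitrite reductase gene nirB 2.17 ± 0.96 (SD, n = 2). NADH dehydrogenase I genes were higher in 6 of 13 and lower in 1, the same adjusted over the list alone (median 0.56, camera adjusted p = 0.0387, adjusted p = 0.557 with an estimated correlation). Among 10000 random lists matched on intensity its median stood at percentile 91.1, short of the outer 2.5% on either side. The genes nuoB, nuoA and nuoC were 2.29 ± 0.34, 2.00 ± 0.31 and 1.70 ± 0.09 (SD, n = 2). ATP synthase genes were higher in 4 of 9 and lower in 1, the same adjusted over the list alone, and did not pass (median 0.51, 0.73 on array 1 and 0.28 on array 2, camera adjusted p = 0.234). Its members atpI, atpC and atpB were 2.64 ± 0.33, -1.40 ± 0.30 and 1.12 ± 0.22 (SD, n = 2). TCA cycle genes did not pass (median -0.62, camera adjusted p = 0.0654), with 7 of 14 lower and 2 higher, the same adjusted over the list alone. They passed with the Agilent processed signals, loess fitted on K-12 probes and ranks, and their median turned to 0.40 when centred on all probes and was -0.25 when centred on K-12 probes. Citrate synthase, gltA, was -2.43 ± 0.14, aconitase B, acnB, -2.02 ± 0.03, and lpd -1.51 ± 0.01 (SD, n = 2).

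Histidine synthesis was lower in 8 of 8 genes, the same adjusted over the list alone (median -1.45, camera adjusted p = 0.00502, adjusted p = 0.557 with an estimated correlation). The list did not pass when centred on K-12 probes, with a median of -0.87. It passed when centred on all probes, with a median of -0.22 against 0.59 for all genes. Its genes hisI, hisD and hisB were -1.71 ± 0.14, -1.71 ± 0.02 and -1.62 ± 0.04 (SD, n = 2). Cysteine and sulfur assimilation did not pass (median -0.50, camera adjusted p = 0.0627), with 11 of 24 lower and 3 higher, the same adjusted over the list alone, and passed with the Agilent processed signals, when centred on all probes or on K-12 probes, with loess fitted on K-12 probes, on ranks and among random lists. The sulfate transport genes cysP, cysU and cysW were -2.52 ± 0.27, -2.37 ± 0.11 and -2.28 ± 0.18 (SD, n = 2). Branched-chain amino acid synthesis did not pass (median -0.024, 0.067 on array 1 and -0.16 on array 2, camera adjusted p = 0.605), with 3 of 13 higher and 6 lower, the same adjusted over the list alone. The acetolactate synthase genes went apart, with ilvN at -2.52 ± 0.05 and ilvB at -2.48 ± 0.09 against ilvI at 2.48 ± 0.17 (SD, n = 2). Arginine synthesis did not pass (median 0.44, camera adjusted p = 0.594), with 4 of 9 higher and 1 lower, the same adjusted over the list alone; argH was -1.47 ± 0.56, argF 1.33 ± 0.25 and argC 0.90 ± 0.39 (SD, n = 2). Methionine synthesis did not pass (median -0.0072, 0.17 on array 1 and 0.025 on array 2, and mean -0.0016 against an upward test, camera adjusted p = 0.973), with 1 of 13 higher and 1 lower, and 0 higher and 1 lower adjusted over the list alone. Its called members were metE at -0.96 ± 0.09 and metB at 0.71 ± 0.35 (SD, n = 2), the latter 0.46 on array 2.

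Ribosomal protein genes did not pass (median 0.012, -0.23 on array 1 and 0.33 on array 2, camera adjusted p = 0.769), with 9 of 52 higher and 9 lower, and 9 higher and 7 lower adjusted over the list alone. The genes rpsU, rpsT and rpsL were 2.06 ± 0.14, 1.65 ± 0.49 and 1.14 ± 0.46 (SD, n = 2). Flagella and chemotaxis had 32 of 48 members measured, of which 1 was higher and 2 lower, the same adjusted over the list alone, and did not pass (median 0.11, 0.36 on array 1 and -0.13 on array 2, camera adjusted p = 0.931). Centred on K-12 probes, the list passed with a median of -0.56, while its loess median stood at percentile 98.95 of random lists. The gene cheZ was -1.42 ± 0.41 and flgN 1.06 ± 0.08, while fliI was -1.11 ± 1.61 (SD, n = 2) and rested on array 1, at -2.25 there and 0.021 on array 2. Outside the lists, the outer membrane stress gene bhsA was -6.96 ± 0.41 and nrdH, which encodes a glutaredoxin-like electron donor of ribonucleotide reductase, was -6.75 ± 0.07 (SD, n = 2).

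**Figure D3:**
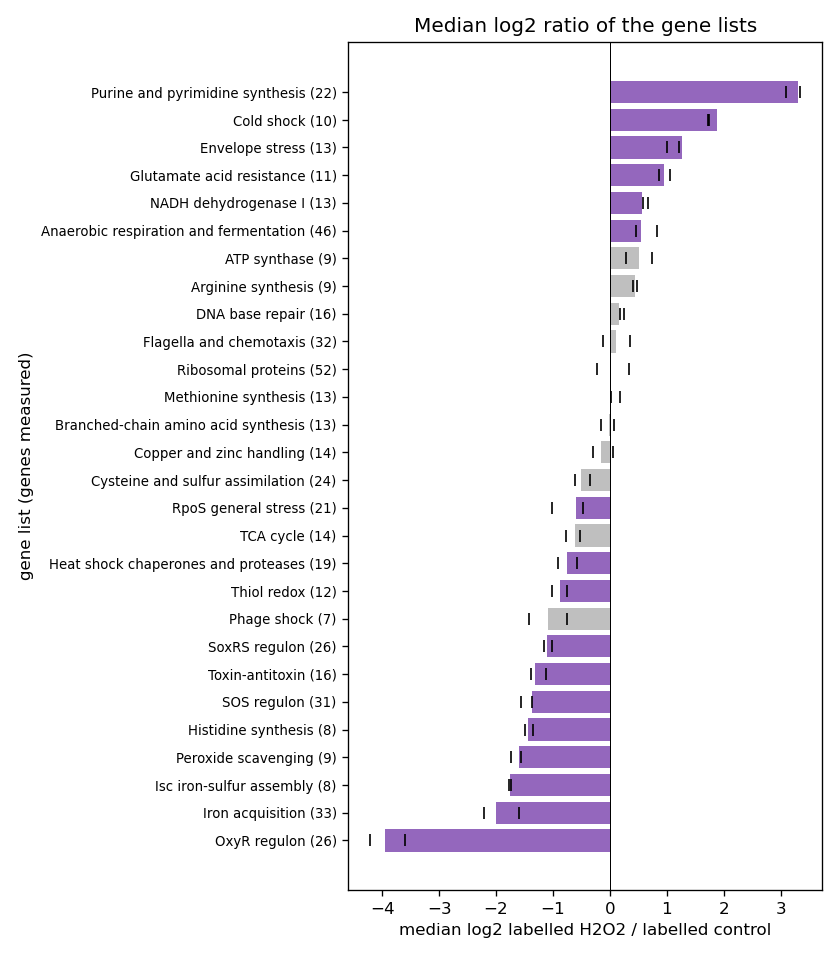
Median log2 ratio of labelled H2O2 over labelled control in each of 28 gene lists, with ticks for the median on each of the 2 arrays and purple bars for the 17 lists that passed with camera. Medians run from -3.95 for the OxyR regulon to 3.31 for purine and pyrimidine synthesis, and those of SoxRS, heat shock and thiol redox turned positive when arrays were centred on all probes, where the median of all genes was 0.59, but stayed negative when centred on K-12 probes, at -0.49, -0.21 and -0.27.

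Probes annotated to strains other than K-12 numbered 6405. Their spots were well above background for 39.3% and 52.7% in the RNA labelled H2O2 on arrays 1 and 2, and for 60.3% and 41.6% in the RNA labelled control. On each array the larger share was in Cy5, whichever RNA it carried. Negative control spots reached between 0.58% and 1.40% in the same channels. The median log2 ratio of these probes was -0.0060.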

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

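The test of background at probes for other strains was chosen only after the result was seen, and the test of shared signal with K-12 genes before. Spots of probes annotated to other E. coli strains were well above background in all 4 channel measurements for 35.8%. Negative control spots reached 0.21%, and the contrast marked the probes as signal outside the main comparison. All negative control spots hold 1 probe, so they do not show the background of varied sequences. Other control spots, of 59 probes, reached 31.6%. At the 2327 probes for other strains above background in all channels, the ratios of labelled H2O2 over labelled control correlated at 0.79 between the arrays. For the 1415 of them without the name of a K-12 gene the correlation was 0.66. Both values argue against nonspecific background as the whole source. By the filter used for genes, signal for at least 1 condition on both arrays, 2787 of the 6405 probes were above background, 81.6% of those with a K-12 name and 34.4% of the rest. Across the 1010 of these with the name of a measured K-12 gene, log2 ratios correlated with that gene at 0.95. Cross-hybridization of K-12 transcripts is therefore a candidate explanation for the named probes. For the 5163 probes without a shared name it stays open, and no biological explanation was tested.

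E1A spike-in control spots were well above background in all 4 channel measurements for 42.5%, against 0.21% of negative control spots. Their share was 83% on array 1 and 71% on array 2 in Cy5, and 45.5% and 48% in Cy3. These values do not tell spike-in RNA from nonspecific signal.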

How the results depend on the processing

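The added alternatives, chosen only after the result was seen, were the ordinary test with 1 residual degree of freedom, a prior of 4 degrees of freedom and centring on K-12 probes well above background. Scaling between arrays and the median of probes changed no reported ratio, and the deposited ratios equal the Agilent processed signals, so these 3 stand outside the counts that follow. Of 909 comparisons of named genes with alternatives that carry a test, 890 kept direction and side of the threshold, 17 lost the call and 1 gained it. Centring on all probes gave 16 of the 17 lost calls. In 1 comparison a gene that had not passed changed direction, and 0 genes that had passed did. Of 308 such comparisons of gene lists, 259 kept both, 26 lost the call, 17 of these with an estimated correlation, and 8 gained it. In 12 a list that had not passed changed direction, and 3 lists that had passed turned. The 3 did so when arrays were centred on all probes, with medians of 0.17 (SoxRS), 0.44 (heat shock) and 0.38 (thiol redox), against -0.49, -0.21 and -0.27, all passing, when centred on K-12 probes. Of lists that had not passed, medians turned to 0.40 (TCA), 0.12 (phage shock), 0.40 (copper and zinc), 0.68 (methionine) and 1.25 (branched-chain) when centred on all probes, and to -0.56 (flagella), 0.025 (methionine) and 0.60 (branched-chain) when centred on K-12 probes. Centring on all probes gave 1885 genes higher, 384 lower and 1615 at least 2-fold on both arrays, and moved the median of all genes to 0.59; centring on K-12 probes gave 1384, 1342 and 1354, with a median of -0.058. The count of changed genes was 1357 with a 2-fold minimum, 1082 against a fold of 1.5, 1448 with the prior of 4 degrees of freedom and 2 in the ordinary test, and 315 genes were at least 4-fold on both arrays. With an estimated correlation 0 lists passed, against 17 in camera at the preset one, 13 when centred on all probes, 17 when centred on K-12 probes and 18 among random lists matched on intensity. The form with an estimated correlation has 1 residual degree of freedom, so it cannot show an effect of correlation between genes. For the OxyR list the estimate was -0.015, below the preset 0.01, yet the unadjusted camera p went from 2.05e-34 to 0.046. The correlation of the arrays was -0.90 with the Agilent processed signals and the deposited ratios, which are the same values, -0.91 at an offset of 16 and -0.92 under either centring. Without each array in turn, values with no test, fliI ranged from -2.25 to 0.021. Apart from what their construction shows, the cause was not tested. Signal over background limits 51 genes, whose folds are bounds.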

Other observations

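All gene families in this paragraph and the next were chosen only after the result was seen, as were the tests of label exchange and dye bias; the tests of neighbours and of the replication origin were chosen before. Genes were grouped by the shared stem of their names, with at least 4 measured genes, and 31 of 241 stems passed with camera. With an estimated correlation, which leaves 1 residual degree of freedom, 0 passed, the adjusted p being 0.988 for each stem named here. The betaine synthesis and uptake genes (bet) were lower in 4 of 4 in the RNA labelled H2O2, with a median log2 ratio of -4.25 and betB at -4.58. Cytochrome bo oxidase genes (cyo) were lower in 4 of 5 (median -2.02), putrescine utilization genes (puu) in 7 of 7 (median -1.68), and the aromatic acid efflux genes (aae) in 4 of 4 (median -1.69). Deoxyribonucleoside degradation genes (deo) were lower in 4 of 5, with deoC at -3.86, while the repressor gene deoR was higher at 1.33. The medians of these 5 families kept their sign when arrays were centred on all probes.

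Higher families in the RNA labelled H2O2 included the periplasmic nitrate reductase (nap, 7 of 7, median 1.45), the periplasmic nitrite reductase (nrf, 7 of 7, median 1.57), hydrogenase 1 (hya, 6 of 6, median 1.53) and cytochrome c maturation (ccm, 8 of 8, median 1.60). Acetyl-CoA carboxylase genes (acc) were higher in 4 of 4, led by accB at 3.08, and isoprenoid synthesis genes (isp) in 8 of 8 (median 1.52). Peptidoglycan endopeptidase genes (mep) were higher in 5 of 5 (median 2.12), arginine transport genes (art) in 5 of 5 (median 1.92), ribose uptake genes (rbs) in 6 of 6 (median 1.65), and gln genes in 8 of 11 (median 1.34), with glnD lower at -1.20.

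The peroxide-induced genes katG, ahpC, ahpF, dps, grxA, trxC, sufA and mntH were lower in the RNA labelled H2O2 in 8 of 8 cases. A label exchange on 1 array alone was argued against by the correlation of -0.92 between the Cy5 over Cy3 ratios of the arrays. Dye bias was argued against because only 7.69% of the 26 measured OxyR regulon genes, called or not, kept the sign of Cy5 over Cy3 on both arrays. A candidate explanation is that channel labels were exchanged on both arrays: 96.4% of the called SOS regulon genes, known to rise with DNA damage, were also lower in the RNA labelled H2O2. A treated culture whose regulons fell below the untreated one at 10 min stays open and was not tested.

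Neighbouring genes on the same strand had log2 ratios that correlated at 0.57 over 2897 pairs, against 0.12 over 1244 pairs on opposite strands. The difference of 0.45 is consistent with shared transcription of neighbours on the same strand. The log2 ratio showed little relation to distance from the replication origin, with a Spearman correlation across genes of 0.051, and of 0.046 and 0.055 on the single arrays.

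The filter removed 120 K-12 genes, most of them without enough signal for the same condition on both arrays. A few were lost to spots marked as outliers. Of the 120, 11 stood side by side along the chromosome, from cheY through cheB, cheR, tap, tar, cheW, cheA, motB, motA and flhC to flhD. The longest such run in 1000 shuffles of the gene order was 4 genes. All 11 belong to the flagella and chemotaxis list. The shuffles moved genes singly, although neighbours on the same strand tend to have like log2 ratios. They thus cannot tell whether the run is longer than shared transcription of neighbours would give. In this stretch, cheR, tap and tar had no channel above background on either array. Among all 45 genes without any such channel the longest run was 3 genes, equal to the longest in shuffles, 3, which also moved genes singly. Besides cheR, tap and tar, a run of this length was flhE, flhA and flhB, which the filter also removed. The run of 11 was chosen after its values were seen.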
